A study of Homo sapiens with 24 samples.

How the data were processed

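RNA was measured by sequencing in 24 libraries of HepG2 cells, a human hepatocellular carcinoma line, which per the labels carried a stable lentiviral short hairpin RNA: a control hairpin (shCtrl), a hairpin against SETD2 (shSETD2) or a hairpin against METTL14 (shMETTL14). Per the labels, cells were selected with puromycin at 1 ug/mL and treated with actinomycin D, an inhibitor of transcription, at 5 ug/mL for 0, 1, 3 or 6 h. Line and time make 12 groups of 2 libraries, which the series' design text calls biological replicates; how the cultures were kept apart is not given in the sources used here, so p-values measure only the spread between these libraries. Group and replicate number were taken from the sample titles.

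The gene-level count values were used as the authors deposited them, and per the submitters' processing notes cutadapt, TopHat and HTSeq 0.6.1p1 were among the tools and GRCh37 was the genome build. The order and settings of those tools, the annotation release and whether the counting used strand are not given in the sources used here, so overlapping and antisense genes are named as uncertain. RPKM values (reads scaled by gene length and library size) stand beside the counts in the same deposited table; the authors' formula for them is not given in the sources used here. A second table holds a half-life in hours per gene and line, as the authors deposited it; per the series' design text, half-lives were derived from expression at 1, 3 and 6 h relative to untreated cells. The labels' extraction protocol says that ERCC spike-in RNA was added to the total RNA; the count table used here holds 0 ERCC entries, so no scaling to spike-ins was run and all values are relative to the other RNA of a library.

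The count table lists 34618 genes, of which 9318 had no count in any library; 29 symbols had been turned into day numbers, and 28 of those genes are named by gene ID. A further 180 entries share a symbol with another entry. Columns were matched to samples by name, and 0 value columns were left without a sample. Library totals ran from 18.3 to 31.4 M counts (median 24.0 M), so 3 counts corresponded to between 0.0955 and 0.164 CPM. Expression levels are given as CPM (counts relative to the library total, scaled by TMM) computed here from the deposited counts.

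Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, two-sided, glmQLFit with the robust option and glmQLFTest), with TMM scaling, filterByExpr over the 12 groups and Benjamini-Hochberg adjustment at 0.05. All 24 libraries entered 1 model with a mean per group and 12 residual degrees of freedom; 14887 genes passed the filter, and the biological coefficient of variation was 5.04%. Each adjusted p in the text is from that test unless another is named. At 0 h each knockdown line was compared with shCtrl, and the knockdown lines with each other. Change under actinomycin D is the least-squares slope of the group means on hours (log2 per h); a decay slope difference is the slope of a knockdown line minus that of shCtrl, so a negative value means a faster fall or a smaller rise than in shCtrl relative to the rest of the RNA. Adjusted values for SETD2 and METTL14 at single times come from the same model.

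Gene lists were fixed before the data were examined: 28 lists, of which the 25 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. They cover the m6A writer complex, m6A readers and erasers, H3K36 methylation enzymes and readers, m6A targets named in earlier work, hepatocyte secreted proteins, liver transcription factors, cytochromes and drug metabolism, cholesterol synthesis, p53 targets, interferon response, immediate early and AU-rich element genes, ribosomal proteins, mitochondrially encoded genes, nuclear-encoded oxidative phosphorylation, proliferation, unfolded protein and integrated stress response, hypoxia and glycolysis, Wnt and beta-catenin targets, matrix, adhesion and cytoskeleton, lipid storage and fatty acid metabolism, noncoding RNAs, replication-dependent histones, ZNF-named genes and RNA decay machinery. The last 4 lists hold markers of other cell types: fibroblasts, blood and immune cells, HEK293T cells as virus producers, and endothelial and stellate cells. Counts of members past the threshold are over all genes tested, with the count adjusted over the list alone beside them.

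The rule for naming genes was also fixed before the data were examined. It takes SETD2, METTL14, MYC, FSCN1, TK1 and MARCKSL1 in every comparison; the 8 largest rises and 8 largest falls past the threshold among genes with a group mean of at least 5 CPM; and up to 3 members per list with the smallest p past the threshold. At 0 h the largest changes also needed both libraries of one line above both of the other, and for decay the same sign of the slope difference in replicate 1 and in replicate 2. The rule gave 93 genes for shSETD2 and 97 for shMETTL14 at 0 h, 96 for the slope in shCtrl, and 77 and 70 for the slope differences, and the text names a part of them.

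Correlations across genes used 10042 genes with at least 5 CPM, and 10 simulated data sets of unchanged lines against the same controls give the value expected from shared controls. Half-lives were recomputed from the deposited RPKM values as ln 2 over the mean decay constant at 1, 3 and 6 h, and from a least-squares slope. Transcript GC content came from GENCODE v29 transcripts; the GC trend of each library was fitted by loess (span 0.3) and removed as an offset, an alternative chosen after seeing the data.

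The tests were tried on simulated counts drawn from the real means and library sizes, with 200 genes changed. For shSETD2 at 0 h the test found 27.4% of genes changed by 0.3 log2 and 82.5% of those changed by 1 log2, with 1 false call among 14344 genes. For the shSETD2 slope difference it found 13.3% of genes changed by 0.05 log2 per h and 70.1% of those changed by 0.15 log2 per h, with 3 false calls among 14344 genes. With a simulated GC trend between libraries, the shSETD2 slope test made 2476 false calls among 14340 genes, and 8 after the trend was removed. In a camera test over 20 lists and 14887 genes at 0 h, the shifted list was found and 0 others were called. The simulated genes were drawn independently, so this trial does not show how often lists of correlated genes are called falsely.

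Alternatives fixed before the data were examined were RLE size factors, library size only, no filter and a stricter filter (mean of 1 CPM and 10 counts in 12 libraries), an adjusted p under 0.01, glmTreat against 1.5-fold, limma-voom, limma on log2(RPKM + 0.5), DESeq2 1.42.0, a replicate block, only the groups compared, each time point left out, a straight line in hours, 6 h against 0 h alone, and each library left out in turn. Alternatives added after seeing the data were the removal of the GC trend, alone, with the block and without the first shSETD2 6 h library; a least-squares formula and a replaced constant for half-lives; the count of genes called the same way under all 5 scalings (TMM, RLE, library size only, stricter filter, GC trend removed); and label exchanges after each gene's mean level per line was removed. Other software was data.table (1.17.8), Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Absolute RNA amounts, isoforms and m6A itself were not analysed here.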

Results

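Gene expression was measured in HepG2 cells, a human hepatocellular carcinoma line, that carried a control hairpin (shCtrl) or a hairpin against SETD2 or METTL14. SETD2 encodes the enzyme that trimethylates histone H3 at lysine 36, and METTL14 a subunit of the methyltransferase that writes N6-methyladenosine (m6A) on RNA. Each of the 3 lines was sampled before and 1, 3 and 6 h after actinomycin D, which blocks transcription, with 2 libraries per line and time. The design asks which transcripts differ between the lines and whether their RNA is lost at a different rate once synthesis stops. Library totals ran from 18.3 to 31.4 M counts, and the mean of a pair ranged from 19.5 M (shSETD2, 6 h) to 28.5 M (shSETD2, 1 h). Mitochondrial transcripts took between 4.56% and 8.90% of the counts, and the 10 most abundant genes of a library between 12% and 21.6%.

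SETD2 (ENSG00000181555; chromosome 3, 47057919 to 47205457, GRCh37) was lower in the shSETD2 line at every time. Before the drug it stood at 86.1 ± 6.11 CPM against 130 ± 1.33 CPM in shCtrl (SD, n = 2 libraries each), or 66.5% of control (log2 fold change -0.59, SE 0.0646, adjusted p = 1.20e-07). At 6 h it stood at 18.9 ± 3.01 against 41.0 ± 1.32 CPM, or 45.9% of control (adjusted p = 1.81e-10). Over the 4 times SETD2 reached 56.8% of control (adjusted p = 3.11e-15). In shMETTL14 cells its mean over the times was 98.1% of control (adjusted p = 0.470). METTL14 (ENSG00000145388; chromosome 4, 119606523 to 119636588) was lower in the shMETTL14 line, at 14.5 ± 0.762 against 29.7 ± 0.532 CPM before the drug, or 48.8% of control (log2 fold change -1.03, SE 0.0992, adjusted p = 1.26e-08). Over the 4 times it reached 37.4% of control (adjusted p = 6.20e-16). In shSETD2 cells METTL14 was higher, at 38.3 ± 0.437 CPM before the drug (log2 fold change 0.37, SE 0.0923, adjusted p = 0.00260) and 120% of control over the 4 times (adjusted p = 0.000102). It did not pass the test at 3 h (115% of control, adjusted p = 0.111) or at 6 h (110%, adjusted p = 0.383). The call before the drug was lost with scaling by library size alone, with limma on RPKM and without either shCtrl 0 h library (highest adjusted p = 0.101).

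**Figure D1:**
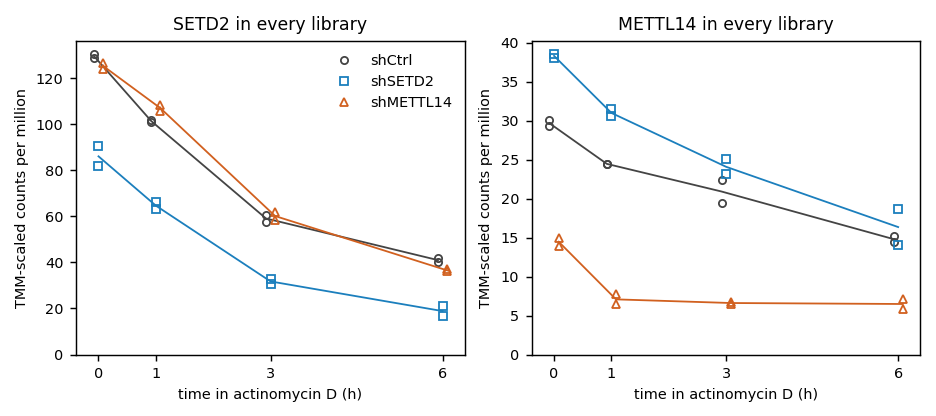
TMM-scaled CPM of SETD2 and METTL14 in each of the 24 libraries, by hours of actinomycin D; points are libraries and lines join the group means of shCtrl, shSETD2 and shMETTL14. SETD2 was lowest in shSETD2 libraries (86.1 against 130 CPM in shCtrl at 0 h) and METTL14 lowest in shMETTL14 libraries (14.5 against 29.7 CPM).

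Several genes with low counts in shCtrl rose in untreated shSETD2 cells. MEP1A (ENSG00000112818; chromosome 6, 46761127 to 46807515), which encodes a meprin metalloprotease subunit, rose 58.9-fold, from 1.11 ± 0.336 to 66.4 ± 0.924 CPM (SD, n = 2; log2 fold change 5.88, SE 0.138, adjusted p = 5.04e-19). PLG (ENSG00000122194; chromosome 6, 161123270 to 161174347), encoding plasminogen, rose from 0.202 ± 0.00658 to 12.1 ± 0.308 CPM. The gluconeogenic enzyme genes PCK1 (chromosome 20, 56136136 to 56141513) and G6PC (chromosome 17, 41052814 to 41065386) rose from 0.885 ± 0.358 to 26.1 ± 0.0384 CPM and from 0.183 ± 0.0345 to 7.60 ± 0.495 CPM. ALB (ENSG00000163631; chromosome 4, 74262831 to 74287129), encoding albumin, rose 3.68-fold, from 4875 ± 98.8 to 17919 ± 91.8 CPM (log2 fold change 1.88, SE 0.0348, adjusted p = 1.31e-20). Among the largest falls were ZNF114 (log2 fold change -2.81), CCND2, encoding cyclin D2 (-2.55), and IL11, encoding interleukin 11 (-2.48). TUBB2B also fell (-2.56). ZNF114 overlaps CARD8 and TUBB2B overlaps PSMG4, so their counts are uncertain.

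Hepatocyte functions rose as groups. Of 47 hepatocyte secreted protein genes 42 rose and 1 fell (43 called adjusted over the list alone, median log2 fold change 0.86, camera adjusted p = 2.90e-27). KNG1 (3.52) and ITIH3 (2.21) were among them. Of 35 cytochrome and drug metabolism genes 27 rose and 1 fell (29 over the list alone, median 1.03, camera adjusted p = 1.05e-11). UGT2B4 stood at 2.87 and CYP3A7 at 2.18. Cholesterol synthesis rose in 22 of 24 members with 0 falls (22 over the list alone, median 1.26, camera adjusted p = 2.52e-18). HMGCS1, whose product makes HMG-CoA, went from 196 ± 1.74 to 861 ± 6.07 CPM, and FDFT1, encoding squalene synthase, rose by 1.19 log2. Lipid storage and fatty acid metabolism rose in 30 of 40 members and fell in 6 (36 over the list alone, median 0.65, camera adjusted p = 8.46e-12). FABP1, encoding a fatty acid binding protein (2.73), LPIN1 (2.06) and SCD, encoding the stearoyl-CoA desaturase (1.30), were higher. HNF4A (0.59) and NR1H4, encoding the bile acid receptor (0.82), were higher. They are among 26 liver transcription factors of which 13 rose and 6 fell (20 over the list alone, median 0.23, camera adjusted p = 0.147, or 0.0291 with the GC trend removed).

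Replication-dependent histone genes rose in 13 of 23 members with 0 falls (13 over the list alone, median 0.95, camera adjusted p = 5.96e-06). HIST1H1C went from 6.17 ± 0.396 to 35.2 ± 1.34 CPM. Proliferation genes rose in 29 of 48 members and fell in 1 (33 over the list alone, median 0.27, camera adjusted p = 1.20e-05). BIRC5 (0.63) and MCM6 (0.57) were among the risen. Mitochondrially encoded genes rose in 12 of 13 members with 0 falls (13 over the list alone, median 0.50, camera adjusted p = 8.47e-09, adjusted p = 0.0573 with an estimated correlation). MT-CYB rose by 0.86 and MT-ND2 by 0.64. Ribosomal protein genes rose in 28 of 78 members and fell in 1 (28 over the list alone, median 0.14, -0.02 with scaling by library size alone, camera adjusted p = 0.00118, adjusted p = 0.577 with an estimated correlation).

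Stress and early response genes fell. In the unfolded protein and integrated stress response list 27 of 37 genes fell and 4 rose (31 over the list alone, median -0.48, camera adjusted p = 2.36e-08). HSPA5, the endoplasmic reticulum chaperone BiP, went from 1997 ± 46.5 to 1120 ± 4.91 CPM. ASNS, encoding the asparagine synthetase, fell by 0.89 log2 and CALR by 0.65. Immediate early and AU-rich element genes fell in 27 of 48 members and rose in 7 (36 over the list alone, median -0.26, camera adjusted p = 0.00246). IL11 fell by 2.48 log2 and IER3 by 0.90 log2, while CTGF rose by 0.93 log2. Of 29 p53 targets 15 fell and 3 rose (19 over the list alone, median -0.23, camera adjusted p = 0.00246), and GDF15 fell by 1.34 log2. H3K36 methylation enzymes and readers, SETD2 included, fell in 11 of 24 members with 0 rises (12 over the list alone, median -0.19, camera adjusted p = 0.00207). KDM4B, a histone demethylase gene, stood at -0.88 and WHSC1, a methyltransferase gene, at -0.31. Matrix, adhesion and cytoskeleton genes fell in 29 of 55 members and rose in 12 (42 over the list alone, median -0.24, camera adjusted p = 0.000423, adjusted p = 0.0937 with an estimated correlation). THBS1 and SPARC both stood at -0.93.

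The other lists did not pass the set test in shSETD2 cells. The m6A writer complex had 2 rises and 3 falls among 9 genes (5 over the list alone), METTL3 at -0.19. The median of the list was 0.06 but -0.10 by library size and -0.02 with the stricter filter, and the set test pointed down (adjusted p = 0.646). The m6A readers and erasers had 2 rises and 2 falls among 14 (4 over the list alone), with a median of 0.02 that was negative under each other scaling and a set test that pointed down (adjusted p = 0.834). Earlier m6A targets had 2 rises and 7 falls among 15 (10 over the list alone, median -0.15, adjusted p = 0.0697). Interferon response genes had 15 rises, USP18 (2.07) and IFIH1 (1.01) among them, and 5 falls among 42 (20 over the list alone, median 0.17, adjusted p = 0.147). Wnt targets had 3 rises and 10 falls among 19 (14 over the list alone, median -0.19, adjusted p = 0.0697). Hypoxia and glycolysis genes had 8 rises and 11 falls among 38 (19 over the list alone, adjusted p = 0.534), with a mean of -0.07 and a median of 0.003 that was negative by RLE, library size and the stricter filter. Nuclear-encoded oxidative phosphorylation had 15 rises and 3 falls among 69 (14 over the list alone, median 0.06, negative by library size and with the stricter filter, adjusted p = 0.225). Noncoding RNAs had 7 rises and 1 fall among 24 (7 over the list alone, median 0.13, -0.03 by library size, adjusted p = 0.154), and ZNF-named genes 46 rises and 65 falls among 437 (96 over the list alone, median -0.03, adjusted p = 0.237). RNA decay machinery had 8 rises and 11 falls among 54 (19 over the list alone, median 0.03, negative under each other scaling, set test down, adjusted p = 0.837). DCP2 rose from 60.8 to 148 CPM (log2 fold change 1.28), while SMG1, a kinase gene of nonsense-mediated decay, stood at -0.37 and CNOT3 at -0.46.

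Markers of other cell types moved both ways. RELN, a stellate cell marker, fell from 2369 to 1369 CPM and LYZ, encoding lysozyme, rose from 1066 to 1373 CPM. At low counts VWF, an endothelial marker, rose from 0.0395 to 0.638 CPM and CD3D, a T cell marker, fell by 2.76 log2. Of 6 blood and immune markers 2 rose and 1 fell (3 over the list alone, median 0.30, mean -0.16, adjusted p = 0.837). Of 3 fibroblast markers 1 rose (1 over the list alone, median 0.15, -0.01 by library size). Of 2 markers of HEK293T cells 1 fell (1 over the list alone, median -0.54), and of 4 endothelial and stellate markers 1 rose and 1 fell (2 over the list alone, median 0.14, negative by library size and with the stricter filter). FSCN1, encoding the actin bundler fascin and earlier named as an m6A target, fell to 40.4 ± 2.64 from 119 ± 2.15 CPM (log2 fold change -1.56, adjusted p = 1.08e-11), and MARCKSL1 fell by 0.63 log2 (adjusted p = 1.17e-07). MYC stood at 153 ± 0.190 against 174 ± 2.44 CPM (log2 fold change -0.19, adjusted p = 0.0197), a call lost without either shSETD2 0 h library (highest adjusted p = 0.0964). TK1, the thymidine kinase gene, stood at 0.31 (adjusted p = 0.0454), a call lost with RLE factors, library size alone, the stricter filter, DESeq2, both limma fits and each 0 h library left out (highest adjusted p = 0.354).

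In all, 6041 of 14887 genes passed the test at 0 h, 3221 higher and 2820 lower, and 1129 of these changed by more than 1 log2. As the naming rule required, the genes named as largest changes at 0 h, in both knockdown lines, had both libraries of one line above both of the other. With scaling by library size alone, which moved the median of all genes from 0.02 to -0.14, the split was 2010 higher and 5103 lower, and with the stricter filter 2347 and 3742. The fold changes of shSETD2 at 0 h fell with transcript GC content (Spearman rho -0.309 across 9929 genes, which are not independent). With the GC trend removed 4059 genes were higher and 3139 lower. Under all 5 scalings 1735 genes were higher and 2310 lower. Besides the lists named above with an estimated correlation, the list calls at 0 h in shSETD2 held with an estimated correlation. With the GC trend removed as well, the immediate early and AU-rich element genes had adjusted p = 0.0605.

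In untreated shMETTL14 cells TXNIP, G6PC and LIPH were among the largest rises. TXNIP (ENSG00000117289; chromosome 1, 145438469 to 145442635), encoding a glucose-responsive inhibitor of thioredoxin and glucose uptake, rose 28.4-fold, from 7.19 ± 0.457 to 204 ± 0.159 CPM (SD, n = 2; log2 fold change 4.83, SE 0.0688, adjusted p = 4.13e-23). Its paralog ARRDC4 rose by 3.45 log2. G6PC rose by 5.41, from 0.183 ± 0.0345 to 8.07 ± 0.511 CPM. The lipase gene LIPH rose by 4.81, TNFSF10, encoding the death ligand TRAIL, by 3.69, and the fatty acid oxidation gene CPT1A by 2.50. Among the largest falls were SEMA3A, a semaphorin gene (-2.87), NOTCH1 (-2.45), JDP2 (-2.19) and ASNS. ASNS (ENSG00000070669; chromosome 7, 97481430 to 97501854) went from 233 ± 2.62 to 51.3 ± 1.72 CPM (log2 fold change -2.18, SE 0.0459, adjusted p = 6.80e-20). MYC (ENSG00000136997; chromosome 8, 128747680 to 128753674) fell from 174 ± 2.44 to 104 ± 2.78 CPM (log2 fold change -0.74, SE 0.0627, adjusted p = 1.65e-09). FSCN1 fell to 45.9 ± 2.37 CPM (-1.38).

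The unfolded protein and integrated stress response list fell in 36 of 37 members with 0 rises (36 over the list alone, median -0.95, camera adjusted p = 1.81e-22). HSPA5 (ENSG00000044574; chromosome 9, 127997132 to 128003609) fell to 838 CPM (log2 fold change -1.25, SE 0.0388, adjusted p = 6.80e-17). HERPUD1 fell by 1.62 log2, ATF3 by 1.30 and SESN2 by 1.15. Ribosomal protein genes fell in 74 of 78 members with 0 rises (76 over the list alone, median -0.51, camera adjusted p = 5.89e-22, adjusted p = 0.0900 with an estimated correlation). RPL19 went from 641 ± 25.6 to 308 ± 8.42 CPM, and RPL6, which overlaps PTPN11, fell by 0.57 log2. Proliferation genes fell in 34 of 48 members and rose in 2 (37 over the list alone, median -0.30, camera adjusted p = 1.16e-07). MCM7, which overlaps AP4M1, fell by 0.76 and CCNB1, encoding cyclin B1, by 0.63. RNA decay machinery fell in 29 of 54 members and rose in 6 (36 over the list alone, median -0.20, camera adjusted p = 0.000213). CNOT1, encoding the scaffold of a deadenylase complex, fell by 0.46, XRN2, a nuclear exonuclease, by 0.49 and PABPC1 by 0.57. Noncoding RNAs fell in 14 of 24 members and rose in 4 (19 over the list alone, median -0.41, camera adjusted p = 0.00298). The small nucleolar RNA hosts GAS5 (-0.78) and SNHG1 (-0.65) fell, and NEAT1, the paraspeckle scaffold, rose by 0.86.

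H3K36 methylation enzymes and readers fell in 13 of 24 members with 0 rises (14 over the list alone, median -0.24, camera adjusted p = 0.00142), DNMT3B by 0.71 and SUPT6H by 0.43. Earlier m6A targets fell in 10 of 15 with 0 rises (10 over the list alone, median -0.24, camera adjusted p = 0.00352), CTNNB1, encoding beta-catenin, by 0.37. The m6A writer complex, METTL14 included, fell in 5 of 9 members with 0 rises (5 over the list alone, median -0.30, camera adjusted p = 0.0272, adjusted p = 0.0900 with an estimated correlation). METTL3 fell by 0.38 and METTL16 by 0.33. The reader gene YTHDF1 fell by 0.94 log2, in a list of 14 readers and erasers with 3 rises and 7 falls (11 over the list alone, median -0.18, camera adjusted p = 0.0520). GAS5, CNOT1, SUPT6H, CTNNB1 and METTL3 overlap ZBTB37, SETD6, SDF2, ULK4 and TOX4 in that order, so their counts are uncertain.

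Hepatocyte secreted protein genes rose in 30 of 47 members and fell in 6 (37 over the list alone, median 0.63, camera adjusted p = 2.18e-08). ITIH3 rose by 2.65 log2 and F5, encoding coagulation factor V, by 1.65 log2. Interferon response genes rose in 24 of 42 members with 0 falls (24 over the list alone, median 0.41, camera adjusted p = 5.66e-06). OAS1 rose by 1.24, DDX58, the RNA sensor RIG-I, by 1.10 and BST2 by 0.92. Cytochrome and drug metabolism genes rose in 14 of 35 members and fell in 6 (21 over the list alone, median 0.25, camera adjusted p = 0.0252, adjusted p = 0.0833 with an estimated correlation). Cholesterol synthesis had 4 rises and 8 falls among 24 (12 over the list alone, median -0.05, 0.01 by library size, camera adjusted p = 0.356). Matrix genes had 21 rises and 21 falls among 55 (42 over the list alone, median -0.14, mean 0.14, set test up, adjusted p = 0.807). Blood and immune markers had 3 rises among 6 (4 over the list alone, median 0.73, camera adjusted p = 0.0509). Of 3 fibroblast markers 3 rose (3 over the list alone), PDGFRB to 22.5 ± 1.54 CPM. Of 4 endothelial and stellate markers 3 rose and 1 fell (4 called over the list alone). LYVE1 rose to 3.07 ± 0.148 CPM, and RELN fell from 2369 ± 18.6 to 1499 ± 23.8 CPM.

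Of the 14887 genes, 7166 passed the test in shMETTL14 at 0 h, 3433 higher and 3733 lower, and the stricter filter gave 2552 higher and 4409 lower. Under all 5 scalings 2511 were higher and 2969 lower. MARCKSL1 stood at -0.24 (adjusted p = 0.00667), a call lost with limma on RPKM, and TK1 at 0.17 (adjusted p = 0.243). Besides those named above with an estimated correlation, the list calls at 0 h in shMETTL14 held with an estimated correlation. With the GC trend removed as well, the earlier m6A targets and the secreted proteins both had adjusted p = 0.0537 and the noncoding RNAs adjusted p = 0.0574.

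**Figure D2:**
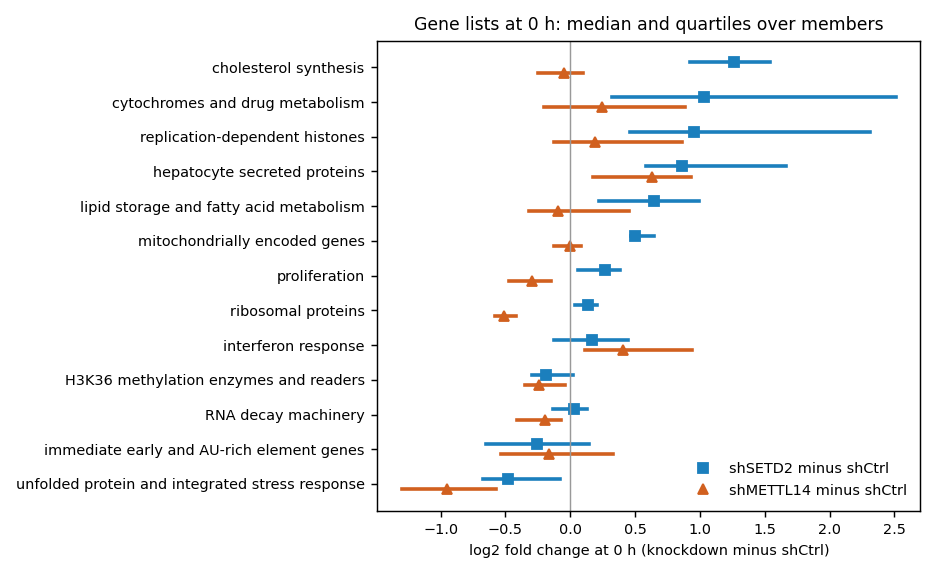
Median (points) and quartiles (bars) of log2 fold changes at 0 h against shCtrl over the tested members of 13 gene lists; squares are shSETD2 and triangles shMETTL14. Unfolded protein and stress response genes lay below 0 in both lines (medians -0.48 and -0.95), cholesterol synthesis was at 1.26 in shSETD2 and -0.05 (0.01 by library size) in shMETTL14, and ribosomal proteins at 0.14 (-0.02 by library size) and -0.51.

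Both knockdowns shared directions at 0 h for many genes. The lists share 1394 genes higher and 1293 lower in both lines, against 743 and 707 for independent lists of those sizes, and 515 and 432 genes went opposite ways, against 808 and 650. Genes higher in both included G6PC and CDH1, encoding E-cadherin (1.75 in shSETD2, 1.46 in shMETTL14), and genes lower in both included HSPA5, ASNS and FSCN1. Across 10042 genes, which are not independent of each other, the fold changes correlated at Pearson r = 0.396, while unchanged lines simulated against the same controls gave 0.498. Their covariance was 0.0862 against 0.00481 simulated. The simulated covariance already holds the spread between the shared control libraries, which argues against that spread as the source of the excess. A feature common to both shCtrl libraries at 0 h would still enter both fold changes. The controls were not split at 0 h.

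The knockdown lines were also compared directly. At 0 h 7767 genes differed, 4342 higher in shSETD2 and 3425 higher in shMETTL14 (2330 and 5787 with scaling by library size, which moved the median of all genes from 0.03 to -0.18). Cholesterol synthesis was higher in shSETD2 in 23 of 24 members with 0 lower (23 over the list alone, median 1.27, camera adjusted p = 1.05e-15). Proliferation genes were higher in 43 of 48 with 2 lower (45 over the list alone, median 0.55, adjusted p = 5.17e-13) and the stress response list in 27 of 37 with 1 lower (30 over the list alone, median 0.60, adjusted p = 1.83e-09). Ribosomal proteins were higher in 75 of 78 with 0 lower (76 over the list alone, median 0.65, adjusted p = 7.73e-23, adjusted p = 0.0949 with an estimated correlation). Interferon response genes were lower in shSETD2 in 16 of 42 members and higher in 3 (19 over the list alone, median -0.22, adjusted p = 0.00578, adjusted p = 0.0983 with an estimated correlation).

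Under actinomycin D in shCtrl cells, immediate early genes and liver transcription factors fell, while hepatocyte secreted protein and nuclear-encoded oxidative phosphorylation genes gained share. BAMBI, encoding a TGF-beta pseudoreceptor, had among the steepest falls, -0.94 log2 per h (SE 0.0294, adjusted p = 7.01e-18), from 29.1 ± 0.198 to 0.585 ± 0.0936 CPM after 6 h (SD, n = 2). RHOB (ENSG00000143878; chromosome 2, 20646835 to 20649200), a small GTPase gene, fell at -0.84 log2 per h (SE 0.00920, adjusted p = 1.46e-25), from 478 ± 5.75 to 15.1 ± 0.350 CPM. TRIB1, DDIT4 and FADD fell at -0.86, -0.85 and -0.83. MYC fell at -0.64 log2 per h, from 174 ± 2.44 to 10.4 ± 1.20 CPM, SETD2 at -0.28 and METTL14 at -0.16. Among the largest rises were MIR663A (0.70), a locus in repeat-rich sequence whose counts are uncertain, NEAT1 (0.37), from 119 ± 1.08 to 788 ± 13.4 CPM, and TPM2, a tropomyosin gene (0.33). Values are shares of a library, so a rise need not mean more RNA.

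Immediate early and AU-rich element genes fell in 47 of 48 members with 0 rises (47 over the list alone, median -0.44 log2 per h, camera adjusted p = 1.81e-15). NFKBIA stood at -0.84 and BTG2 at -0.67. ZNF-named genes fell in 330 of 437 members and rose in 29 (363 over the list alone, median -0.18, adjusted p = 3.63e-15), ZNF703 at -0.62. Liver transcription factors fell in 20 of 26 and rose in 2 (24 over the list alone, median -0.27, adjusted p = 4.13e-06). Among them were FOXA1, which overlaps TTC6, at -0.66, GATA4 at -0.62 and CEBPA at -0.60. The m6A writers fell in 8 of 9 members with 0 rises (8 over the list alone, median -0.24, adjusted p = 0.000180). WTAP, which overlaps SOD2, fell at -0.32, and the reader genes YTHDF2 and YTHDF1 at -0.53 and -0.40. Also lower were p53 targets (20 of 29, 5 higher, 25 over the list alone, median -0.10, adjusted p = 0.000582), PPM1D at -0.65. So were Wnt targets (12 of 19, 3 higher, 15 over the list alone, median -0.11, adjusted p = 0.00202).

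Nuclear-encoded oxidative phosphorylation genes rose in 68 of 69 members with 0 falls (68 over the list alone, median 0.15, adjusted p = 1.81e-15), NDUFA4 at 0.17. Ribosomal proteins rose in 70 of 78 with 0 falls (70 over the list alone, median 0.16, adjusted p = 2.79e-15, adjusted p = 0.153 with an estimated correlation), RPS4X, which overlaps PIN4, at 0.17. Hepatocyte secreted proteins rose in 39 of 47 and fell in 1 (41 over the list alone, median 0.15, adjusted p = 8.24e-12), SERPINA1, encoding alpha-1-antitrypsin, at 0.18 and FGA, a fibrinogen chain, at 0.17. Matrix genes rose in 37 of 55 and fell in 5 (42 over the list alone, median 0.13, adjusted p = 4.13e-06), fibronectin FN1 at 0.16. Lipid genes rose in 31 of 40 with 3 falls (34 over the list alone, median 0.09, adjusted p = 1.50e-05), and cytochrome genes in 21 of 35 with 1 fall (22 over the list alone, median 0.11, adjusted p = 0.00202). Hypoxia and glycolysis genes rose in 24 of 38 and fell in 11 (35 over the list alone, median 0.10, adjusted p = 0.0118, adjusted p = 0.0892 with an estimated correlation). Mitochondrially encoded genes fell in 9 of 13 members and rose in 1 (10 over the list alone, median -0.03, adjusted p = 0.00950, adjusted p = 0.321 with an estimated correlation). MT-CYB fell at -0.47 log2 per h. Blood and immune markers rose in 5 of 6 with 0 falls (5 over the list alone, median 0.18, adjusted p = 0.0468, adjusted p = 0.117 with an estimated correlation).

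In shCtrl 10579 genes changed with time, 5632 rising and 4947 falling in share. Library size alone gave 3360 rising and 6788 falling and moved the median of all genes over 6 h from 0.14 to -0.22 log2. FSCN1 (0.07), MARCKSL1 (0.07) and TK1 (0.10) rose with TMM and were not called the same way under all 5 scalings. With an estimated correlation the list calls held besides those given above, and nuclear-encoded oxidative phosphorylation had adjusted p = 0.0786 once the GC trend was removed too.

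In shSETD2 cells CTGF, TARS and PIM1 were among the transcripts lost faster under actinomycin D than in shCtrl. CTGF (ENSG00000118523; chromosome 6, 132269316 to 132272513), encoding connective tissue growth factor, had a slope difference of -0.17 log2 per h (SE 0.0116, adjusted p = 3.54e-09). It fell from 322 ± 2.75 to 55.2 ± 1.66 CPM over 6 h, against 170 ± 7.52 to 58.0 ± 0.0976 CPM in shCtrl (SD, n = 2). At 3 h CTGF stood at 136 CPM in shSETD2, or 42.3% of its 0 h level, and at 154 CPM in shCtrl, or 90.7%. The lines thus parted in the first 3 h, and the later fall was similar. A negative difference is a lower slope, a steeper fall or a smaller rise in share than in shCtrl. TARS, a tRNA synthetase gene, had -0.18 log2 per h (SE 0.0132, adjusted p = 9.76e-09). PIM1, a kinase gene, had -0.19, CREBRF -0.24 and the p53 regulator MDM2 -0.14. Higher slopes than in shCtrl were seen for TP53INP2, an autophagy gene that overlaps NCOA6 (0.23 log2 per h, SE 0.0161, adjusted p = 7.40e-09), and the mitochondrial ligase gene MUL1 (0.27). LDHA (ENSG00000134333; chromosome 11, 18415935 to 18429972), encoding lactate dehydrogenase A, had 0.11 (SE 0.0102, adjusted p = 2.42e-07) and stood at 126% of its 0 h level at 6 h. At 3 h LDHA stood at 143% in shSETD2 and 132% in shCtrl. From 3 to 6 h it fell from 547 to 332 CPM in shCtrl and from 968 to 850 CPM in shSETD2. For LDHA the lines thus parted mostly after 3 h, with the late fall in shCtrl. MT-CYB also fell more slowly (0.10 log2 per h, adjusted p = 2.56e-07), to 21.9% of its 0 h level at 6 h against 14.3% in shCtrl.

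JUND (-0.11), GDF15 (-0.12) and SLC38A2 (-0.15) also had lower slopes, and higher ones were seen for HNF4A (0.07) and the noncoding RNA SNHG7 (0.20). Transcripts whose calls rest on single libraries were DUSP5, a phosphatase gene (-0.27, lost without the first shSETD2 6 h library, adjusted p = 0.0537), ZNF92 (-0.26, highest adjusted p = 0.104 with 1 library left out) and IER5L (0.40, highest adjusted p = 0.201). TRIB3, a stress pseudokinase gene, had 0.13 log2 per h, but -0.09 without the 6 h libraries (adjusted p = 0.0494). SETD2 itself had -0.09 log2 per h (SE 0.0167, adjusted p = 0.00145), a call lost without the second shCtrl 0 h library (adjusted p = 0.0579), without the 0 h or the 1 h libraries, with only the groups compared and with limma on RPKM. METTL14 (-0.04, adjusted p = 0.320), MYC (-0.03, adjusted p = 0.409), FSCN1 (0.03, adjusted p = 0.338), MARCKSL1 (-0.003, adjusted p = 0.934) and TK1 (0.01, adjusted p = 0.816) did not pass the test. The values of MYC, MARCKSL1, FSCN1 and TK1 changed sign under other settings.

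Of the gene lists, ZNF-named genes passed the set test for lower slopes in shSETD2, with 49 of 437 lower and 2 higher (68 over the list alone, median -0.05, camera adjusted p = 0.0116, adjusted p = 0.515 with an estimated correlation, 0.128 with the GC trend removed). ZNF121 (-0.14) and ZNF614 (-0.13) were among them. Wnt targets passed only with the GC trend removed (camera adjusted p = 0.0395, adjusted p = 0.190 with an estimated correlation). Immediate early and AU-rich element genes had 8 lower and 3 higher slopes among 48 (15 over the list alone, median -0.02, positive by RLE and with the stricter filter, adjusted p = 0.798). Stress response genes had 8 lower and 7 higher among 37 (20 over the list alone, median -0.003, positive under each other scaling, adjusted p = 0.798). Earlier m6A targets had 3 lower and 0 higher among 15 (4 over the list alone, median -0.02, positive by RLE and with the stricter filter, adjusted p = 0.560).

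The overall direction in shSETD2 depended on the scaling. Of 1182 genes past the test 960 had lower slopes and 222 higher ones, but RLE factors gave 294 lower and 463 higher, library size 487 and 273, and the stricter filter 246 and 1508, with the median difference over 6 h moving from -0.08 to 0.11 log2. Under all 5 scalings 231 genes had lower slopes and 171 higher ones. Without single libraries the count was 489 (second shCtrl 6 h), 648 (first shSETD2 6 h), 738 and 749 (first and second shSETD2 0 h) and 3860 (second shSETD2 6 h). The slope differences rose with transcript GC content (Spearman rho 0.616 across 9929 genes, which are not independent), and 2002 genes, 1686 lower and 316 higher, were called with the GC trend removed. Of the 1182 genes 992 kept call and direction.

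In shMETTL14 cells CYR61, DUSP5, CTGF and XBP1 were lost faster than in shCtrl. CYR61, encoding a matricellular protein (ENSG00000142871; chromosome 1, 86046444 to 86049645), had a slope difference of -0.44 log2 per h (SE 0.0248, adjusted p = 6.13e-11) and fell from 36.8 ± 0.147 to 1.94 ± 0.273 CPM against 39.1 ± 0.823 to 11.3 ± 0.901 CPM in shCtrl (SD, n = 2). DUSP5 had -0.47 (SE 0.0450, adjusted p = 4.46e-07), CTGF -0.28 (SE 0.0123, adjusted p = 1.85e-12). XBP1 (ENSG00000100219; chromosome 22, 29190543 to 29196585), a transcription factor gene of the unfolded protein response, had -0.23 (SE 0.0111, adjusted p = 3.02e-12) and retained 4.68% of its 0 h level at 6 h against 11.5% in shCtrl. MYC fell faster by -0.15 log2 per h (SE 0.0244, adjusted p = 0.000319), retaining 2.90% against 5.95%, a call lost without the 0 h libraries. LDHA had a higher slope than in shCtrl (0.18 log2 per h, SE 0.0102, adjusted p = 6.14e-11) and stood at 167% of its 0 h level at 6 h. At 3 h LDHA stood at 155% in shMETTL14 and 132% in shCtrl. From 3 to 6 h it went from 1097 to 1178 CPM in shMETTL14 and fell from 547 to 332 CPM in shCtrl. Most of this difference thus arose after 3 h, and the same shCtrl 6 h libraries enter the LDHA value of shSETD2. MT-CYB (0.14, adjusted p = 2.54e-10), TP53INP2 (0.20), GCNT3 (0.21, overlapping GTF2A2) and the clock gene NR1D1 (0.42), which lies antisense to THRA so that its counts are uncertain, also had higher slopes.

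Immediate early and AU-rich element genes had lower slopes in 13 of 48 members and higher ones in 2 (18 over the list alone, median -0.05, camera adjusted p = 9.07e-07). DUSP6 stood at -0.23, as did FOXQ1, a gene outside the list. H3K36 methylation enzymes and readers had lower slopes in 6 of 24 with 0 higher (10 over the list alone, median -0.03, adjusted p = 4.57e-06), the demethylase genes KDM4A and KDM2A at -0.11 and -0.10. Wnt targets had lower slopes in 7 of 19 and a higher one in 1 (9 over the list alone, median -0.02, adjusted p = 0.000756), AXIN2 at -0.10 and NKD1 at -0.07. Cholesterol synthesis had lower slopes in 6 of 24 with 0 higher (7 over the list alone, median -0.01, 0.01 with the stricter filter, adjusted p = 0.00146). RNA decay machinery had them in 7 of 54 with 0 higher (11 over the list alone, median -0.02, 0.01 with the stricter filter, adjusted p = 0.00394), TOB1 at -0.15. The m6A readers and erasers had them in 4 of 14 with 0 higher (6 over the list alone, median -0.01, 0.01 with the stricter filter, adjusted p = 0.0276, adjusted p = 0.374 with an estimated correlation), YTHDC1 at -0.09, a nuclear reader gene.

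The stress response list went the other way in shMETTL14, with higher slopes in 10 of 37 and lower ones in 3 (21 over the list alone, median 0.02, adjusted p = 0.000756). DNAJB9, a chaperone gene that overlaps PNPLA8 and THAP5, stood at 0.22, while XBP1 stood at -0.23 and HERPUD1 at -0.18. HSPA1A, a chaperone gene outside the list, also stood at 0.22, and is uncertain as a near-identical copy of HSPA1B. Hepatocyte secreted proteins had higher slopes in 5 of 47 and a lower one in 1 (13 over the list alone, median 0.02, adjusted p = 2.09e-06, adjusted p = 0.0663 with an estimated correlation). Mitochondrially encoded genes had higher slopes in 3 of 13 and a lower one in 1 (7 over the list alone, median 0.02, adjusted p = 0.00264, adjusted p = 0.326 with an estimated correlation). Ribosomal proteins and histones passed as sets (adjusted p = 5.32e-06 and 0.0129, medians 0.02 and 0.04) with 0 single members past the test over all genes or the list alone. With an estimated correlation adjusted p was 0.439 and 0.0499. Noncoding RNAs had 2 higher and 1 lower among 24 (4 over the list alone, median 0.01, negative by library size, adjusted p = 0.0445, adjusted p = 0.0704 with an estimated correlation), LINC00657 at 0.13. The m6A writers had 0 calls among 9 (0 over the list alone; adjusted p = 0.630) and earlier m6A targets 1 higher and 1 lower among 15 (2 over the list alone; adjusted p = 0.630). The remaining list calls for shMETTL14 decay held with an estimated correlation.

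SETD2 (-0.03, adjusted p = 0.415), METTL14 (0.01, adjusted p = 0.891), FSCN1 (0.005, adjusted p = 0.949), MARCKSL1 (0.02, adjusted p = 0.446) and TK1 (0.03, adjusted p = 0.590) did not pass the test for shMETTL14 decay. The values of SETD2, METTL14, FSCN1 and TK1 changed sign under other settings, and METTL14 passed in the other direction without the 6 h libraries (-0.18, adjusted p = 0.00688). In total 775 genes passed, 499 with lower and 276 with higher slopes. RLE factors gave 380 lower and 360 higher, library size 1047 and 175, and the stricter filter 265 and 1397, which moved the median difference over 6 h from -0.02 to 0.12 log2. Under all 5 scalings 262 were lower and 168 higher. The count was 466 without the second shCtrl 6 h library, 475 without the first shMETTL14 6 h library and 486 without the first shCtrl 6 h library. With the GC trend removed 1307 genes had lower and 713 higher slopes. Fits of a knockdown line with shCtrl alone, without the robust option or gene-wise dispersions, called 2460 genes for shMETTL14 and 784 for shSETD2. The main test restricted to the groups compared gave counts near these, so which line had more calls depended on the libraries that entered the fit. Called over 24 libraries, the difference between both knockdown slopes passed for 1430 genes, 477 with higher and 953 with lower slopes in shSETD2 (754 and 427 with RLE factors, 1121 and 315 by library size, 669 and 602 with the stricter filter). Without single libraries that count was 696 (second shMETTL14 6 h), 768 and 903 (first and second shMETTL14 0 h) and 3553 (second shSETD2 6 h).

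**Figure D3:**
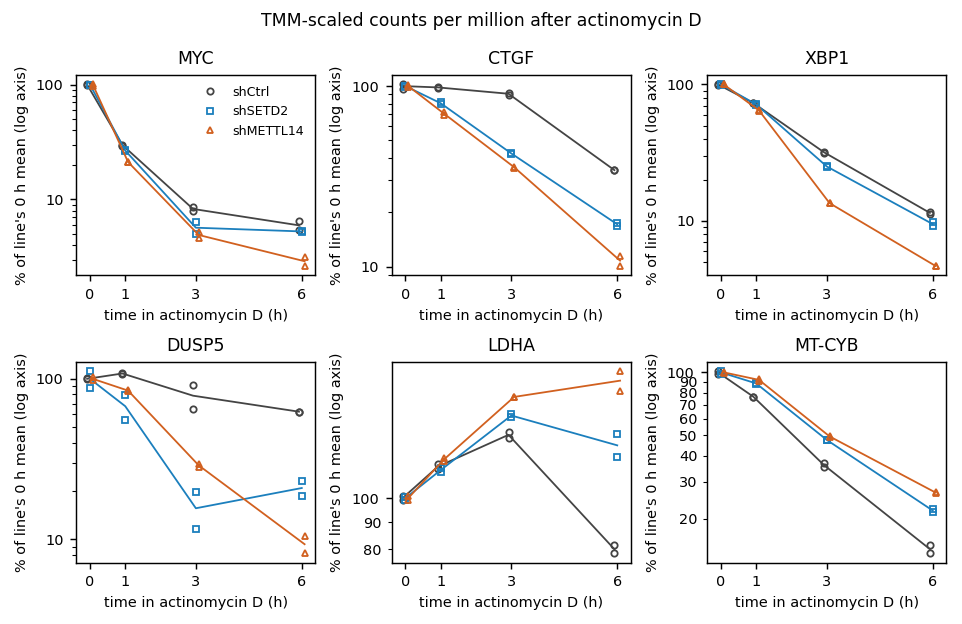
Libraries (points) and group means (lines) as a percent of the same line's 0 h mean (log axis) against hours of actinomycin D for MYC, CTGF, XBP1, DUSP5, LDHA and MT-CYB in shCtrl, shSETD2 and shMETTL14. At 6 h CTGF stood at 34.2%, 17.1% and 10.8% of its 0 h level in the lines in that order, XBP1 at 11.5%, 9.48% and 4.68%, and MYC at 5.95%, 5.27% and 2.90%.

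Both knockdowns shared 140 genes with lower and 77 with higher slopes than shCtrl, against 32.2 and 4.12 for independent lists, and 5 and 23 went opposite ways, against 7.44 and 17.8. Under all 5 scalings 36 genes were lower in both lines, CTGF, DUSP5 and PIM1 among them, 58 higher in both, including LDHA, MT-CYB and TP53INP2, and 11 opposite. Both sets of slope differences subtract the same shCtrl slopes, so shared controls by themselves raise the counts with a shared direction above those of independent lists. Across 10042 genes, not independent of each other, the slope differences correlated at Pearson r = 0.380 (0.491 for simulated unchanged lines on the same controls), with a covariance of 0.000661 (0.000290 simulated). With separate control libraries for each line r was 0.307 or 0.0361, depending on which went with which. Level at 0 h and slope difference over 1, 3 and 6 h were weakly related across the genes, at r = -0.05 in shSETD2 (0.07 with the GC trend removed) and 0.15 in shMETTL14.

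Half-lives in the authors' deposited table were shorter in both knockdown lines, with medians over 7772 genes of 6.02 h in shCtrl, 4.13 h in shSETD2 and 4.31 h in shMETTL14. In the authors' deposited table, the share of genes with a shorter half-life was 88.2% for shSETD2 and 88.8% for shMETTL14, and median ratios to shCtrl were 0.702 and 0.717. For CTGF the authors' deposited table lists 3.03, 1.78 and 1.51 h in shCtrl, shSETD2 and shMETTL14, for MYC 1.42, 1.25 and 1.07 h, and for XBP1 1.67, 1.41 and 1.12 h. In the authors' deposited table METTL14 has 4.38, 2.98 and 3.69 h and SETD2 2.88, 1.98 and 2.30 h. Recomputed from the deposited RPKM values through the mean decay constant, the median ratio was 1.03 in shSETD2, with 46.7% of 6164 genes shorter, and 0.910 in shMETTL14, with 62.1% of 6358 shorter. By a least-squares slope the direction in shSETD2 turned, with a median ratio of 0.954 and 56.3% of 7146 genes shorter, and shMETTL14 had 0.877 and 69.1% of 7367. Genes not matched to the count table or without a positive, finite rate in both lines compared were left out of these. RPKM values are scaled by library size, so the recomputed ratios cannot show a change of decay shared by all RNA. The decay rates behind the authors' deposited table followed the least-squares slope of RPKM (r = 0.999 across genes in each line) plus a constant of 0.00840 per h in shCtrl, 0.0567 per h in shSETD2 and 0.0403 per h in shMETTL14, whose origin is not given in the sources used here.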

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

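The direct tests between the knockdown lines were fixed before the data were examined, and the tests of the GC trend, the half-lives, the stress response genes and the splits were chosen after those results had been seen. The genes, lists and counts of the first paragraphs were picked because a direct test between the knockdown lines passed while the lines were first compared with shCtrl separately. The GC trend, the half-lives and the stress response genes were noticed in the tables.

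Ribosomal protein genes were higher in shSETD2 than in shMETTL14 at 0 h by a median of 0.65 log2 (camera adjusted p = 7.73e-23, adjusted p = 0.0949 with an estimated correlation), with RPS27A at 0.88, RPS18 at 0.86, RPLP0 at 0.79, RPL6 at 0.78 and RPL34 at 0.77, and PABPC1, encoding the poly(A) binding protein, at 0.75. Proliferation genes differed by a median of 0.55, with CCNB1 at 0.89. ACAT2 (1.65), FDFT1 (1.30) and SCD (1.40) stood higher among lipid and sterol enzymes, and GAS5 (1.05) and SNHG5 (1.35) among noncoding RNAs. Of 13 mitochondrially encoded genes 12 were higher (camera adjusted p = 1.18e-06, adjusted p = 0.105 with an estimated correlation), MT-ND1 by 0.93 and MT-ND2 by 0.89. MEP1A (6.75), UGT2B4 (4.17), DKK4 (4.15), NR1H4 (1.81) and METTL14 (1.40), the gene targeted in the other line, were also higher in shSETD2. EEF1A2 (-3.70), NDRG4 (-3.59), DDX58 (-1.37), SPARC (-1.33) and SLC2A3 (-1.20) were lower in shSETD2 than in shMETTL14. RPS27A overlaps CLHC1, RPS18 VPS52, RPL6 PTPN11, GAS5 ZBTB37, and ACAT2 both SOD2 and TCP1, so their counts are uncertain. In all 7767 genes differed at 0 h.

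For decay, 1430 genes differed between the knockdown lines, 696 to 3553 with single libraries left out. Of them 477 had higher and 953 lower slopes in shSETD2, against 754 and 427 with RLE factors. LINC00657 (-0.21 log2 per h), TNFRSF10B (-0.12), MT-CO2 (-0.12), SP1 (-0.11) and MT-CO1 (-0.0747) had lower slopes in shSETD2 than in shMETTL14, where both MT-CO1 and MT-CO2 had higher CPM at 6 h than at 0 h. TNFRSF10B overlaps RHOBTB2, so its counts are uncertain.

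The slope differences of shSETD2 rose with transcript GC content. GC bias between libraries is a likely part of this: the slope difference between both shCtrl series, which share a hairpin, correlated with GC at 0.617. It is unlikely to be the whole cause of the calls, since 992 of 1182 genes kept call and direction after its removal (769 of 775 for shMETTL14). Whether decay itself changed with GC in shSETD2 could not be told, because the 4 pairings of a shSETD2 with a shCtrl series gave correlations of 0.656, 0.789, -0.133 and 0.411. More replicates of the 6 h libraries would tell these apart.

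Shorter half-lives in the authors' deposited table may rest mostly on a constant per line. Replacing it by that of shCtrl removed 87.9% of the median log2 ratio in shSETD2 (7772 genes before, 7368 after) and 61.4% in shMETTL14 (7627 after), as genes not matched to the count table or without a positive rate dropped out. Weak expression is an unlikely cause, as 92.6% of genes with RPKM of at least 1 were still shorter in the authors' deposited table. A true overall difference in decay could also hide in the constant, which was 0.0483 per h larger in shSETD2 than in shCtrl; spike-in counts would decide this.

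Lower stress response genes at 0 h in both knockdown lines are unlikely to come from GC bias or scaling. The higher of both medians was -0.45 log2 with the GC trend removed, and the highest over 4 scalings and both lines was -0.48. Culture state and clonal differences between the stable lines were not tested and could give the same pattern.

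Line labels were also exchanged within time points, 100 splits for each decay comparison. With the real one included, 9 splits for shSETD2 called at least as many genes as the real one (784 in that fit, highest other 6335), for shMETTL14 9 (2460, highest other 8518) and for shSETD2 against shMETTL14 10 (1618, highest other 7928). Splits with several times the real count point to a structure of the samples: they swap whole time points, so differences in level between lines enter the slope. With each line's mean level removed first, the numbers, again with the real one included, were 4 (highest other 3084), 1 (1209) and 1 (1328), so in the last pair no other split reached the real count. Most of these splits put libraries of both lines in a group. Real differences between the lines at that time then widen its spread and lower the count. Low counts in such splits are thus built in, and the ranks do not decide whether the decay calls exceed what chance gives. The fits for splits held only the libraries of the lines compared and used neither the robust option nor gene-wise dispersions. Restricting the main test to those libraries gave 747 genes for shSETD2 and 2467 for shMETTL14, near the counts of these fits.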

How the results depend on the processing

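The GC removal, its combinations, the least-squares half-lives and the replaced constant were chosen after the results were seen; the other settings were fixed before.

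Named-gene calls at 0 h and in shCtrl mostly held, and the decay calls of the knockdown lines depended most on the setting. Of 433 named results 407 were the same with RLE factors, 402 by library size, 428 with limma-voom, 397 with limma on RPKM and 423 with the GC trend removed. A test against 1.5-fold kept 242 of the 433. Of 243 named slope results 128 were the same with a straight line in hours and 232 with 6 h against 0 h alone. Without the 0, 1, 3 or 6 h libraries 155, 187, 223 and 188 of the 243 were the same. A scaling to ERCC spike-ins was not run, as the count table has 0 ERCC entries. Depth of 18.3 to 31.4 M counts limits calls for genes of low expression, and 2 libraries per group limit all slopes. Where no cause is named below, the cause was not tested. Gene values are slope differences in log2 per h, as shSETD2 or shMETTL14 minus shCtrl, and those listed turned sign. CTNNB1 overlaps ULK4, MVK overlaps MMAB and SERPIND1 overlaps PI4KA, so their counts are uncertain.

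Scaling and filter. With RLE factors the count of genes for shSETD2 decay was 757, and by library size only 760, with 1222 for shMETTL14. RLE gave MARCKSL1 in shSETD2 0.0164 and DESeq2 the same 0.0164. Library size alone gave MARCKSL1 0.00675 in shSETD2, FSCN1 -0.00768 and METTL14 -0.000362 in shMETTL14, and SETD2 at 0 h in shMETTL14 0.00640. The stricter filter gave 1662 genes for shMETTL14 decay and, in shSETD2, CTNNB1 0.00502, MARCKSL1 0.0290 and MYC 0.00218. With no filter the agreement at 0 h was 0.461.

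Model and threshold. Adjusted p under 0.01 left 433 genes for shSETD2 decay, 391 for shMETTL14 and 603 for the lines against each other. A test against 1.5-fold left 1107 (shSETD2 at 0 h), 1183 (shMETTL14), 1537 (between them), 5446 (shCtrl slope), and 11, 25 and 23 for the decay comparisons in that order. A straight line in hours left 66, 78 and 143, and METTL14 at -0.00637 in shMETTL14. With only the groups compared shSETD2 decay had 747 genes and shMETTL14 2467, and shSETD2 values were CTNNB1 0.00419, MARCKSL1 0.0282 and MYC 0.00131. Limma on RPKM gave 1248 genes for shMETTL14 decay, FSCN1 -0.00755 there, MARCKSL1 0.00626 in shSETD2 and SETD2 0.00587 at 0 h in shMETTL14.

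Replicate numbers. Of 66 pairs of groups 36 had correlations over 0.1, with a range of -0.196 to 0.650, so the numbers were not taken to pair the libraries. The 36 are all pairs among 9 of the groups, a hint from the data of a tie by number in those. In these 9 the difference between replicates correlated with transcript GC content at Spearman rho -0.362 to -0.831. In shCtrl at 0 h and 1 h and in shSETD2 at 0 h rho was 0.196, 0.168 and 0.0449. This difference was thus uneven over time, and the main test, without a block, did not account for it. A replicate block gave 2015 genes for shSETD2 decay and 2205 for the lines against each other, a block within each line 1902 for shSETD2, and no named call was lost. Of the gene list calls there were 52, with 51 under the block, 36 with an estimated correlation and 54 with the GC trend removed.

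GC trend removed. Counts were 2002 (shSETD2 decay), 2020 (shMETTL14) and 2737 (between them), with the block 2296, 2193 and 2988, and without the first shSETD2 6 h library 2225 between the lines. Values were TK1 -0.0226 and FSCN1 -0.00704 in shSETD2 and FSCN1 -0.00680 in shMETTL14; with the block -0.0218, -0.00677 and -0.00676; without that library TK1 -0.0382 and FSCN1 -0.00902 in shSETD2. Agreement at 0 h was 0.413, and level against decay in shSETD2 turned to 0.0688.

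Time points. Without 0 h the counts were 138 (shSETD2) and 300 (shMETTL14), without 1 h 707 for shSETD2 and 566 between lines, without 3 h 654, 499 and 953, and without 6 h 725 between lines. Without 0 h shSETD2 values were ACSL5 0.0125, MARCKSL1 0.0167 and MYC 0.0310, and shMETTL14 values FSCN1 -0.0554, SERPIND1 -0.00584 and TK1 -0.0165. Without 1 h they were CTNNB1 0.00118, MARCKSL1 0.0314 and MYC 0.00218 in shSETD2, and METTL14 -0.00713 and SETD2 0.000348 in shMETTL14. Without 6 h they were CYP4F3 0.00541, MVK -0.00456, SP1 0.0703 and TRIB3 -0.0862 (adjusted p = 0.0494) in shSETD2, and AURKA 0.0179, SETD2 0.00442 and METTL14 -0.182 (adjusted p = 0.00688) in shMETTL14. With 6 h against 0 h alone MARCKSL1 was 0.000737 in shSETD2 and METTL14 -0.0271 in shMETTL14.

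Libraries left out in turn. Counts ranged from 4579 to 5151 (shSETD2 at 0 h), 6209 to 6402 (shMETTL14), 489 to 3860 (shSETD2 decay), 466 to 1139 (shMETTL14) and 696 to 3553 (between them). FSCN1, decay slope shSETD2 minus shCtrl, ranged from -0.00726 to 0.0683, and CTNNB1, decay slope shSETD2 minus shCtrl, from -0.0298 to 0.00600. The ranges were -0.0390 to 0.0000544 for IGF2BP1, decay slope shSETD2 minus shCtrl, and -0.0259 to 0.0300 for MARCKSL1, decay slope shSETD2 minus shCtrl. They were -0.0498 to 0.00362 for MYC, decay slope shSETD2 minus shCtrl, and -0.0369 to 0.0530 for TK1, decay slope shSETD2 minus shCtrl (the highest without the second shSETD2 6 h library, adjusted p = 0.0344). For FSCN1, decay slope shMETTL14 minus shCtrl, the range was -0.00245 to 0.0336, and for METTL14, decay slope shMETTL14 minus shCtrl, it was -0.0118 to 0.0416.

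Correlations across genes. Agreement at 0 h was 0.311 by Spearman and 0.392 to 0.406 with single replicates, and agreement of decay 0.0361 with the second control for shSETD2 and the first for shMETTL14. Level against decay was -0.0664 in shSETD2 with the slope over all 4 times, -0.0406 with the stricter filter and -0.0441 to -0.0289 with single replicates. In shMETTL14 it was 0.190 over genes past the threshold at 0 h and 0.104 to 0.154 with single replicates.

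Half-lives. The median log2 ratio in the authors' deposited table was -0.426 for shMETTL14 and -0.453 for shSETD2 within 0.5 to 24 h, and with the constant replaced -0.185 and -0.0618. Recomputed, it was (shMETTL14, then shSETD2, where values above 0 are the other direction) -0.136 and 0.0366 by the mean decay constant, -0.190 and -0.0672 by least squares, -0.148 and 0.0286 without replicate 1, -0.125 and 0.0167 without replicate 2, -0.142 and 0.0438 with 0.1 added, and -0.143 and 0.0734 with 1 added.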

Other observations

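The stability tests in this part were chosen before their result was seen.

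Hypoxia, glycolysis and lipid genes went both ways in untreated shMETTL14 cells. Of 38 hypoxia and glycolysis genes 14 rose and 8 fell (24 over the list alone, median 0.14 log2, camera adjusted p = 0.0992). LDHA rose from 415 ± 5.95 to 706 ± 8.47 CPM (SD, n = 2; adjusted p = 7.11e-12) and NDRG1, a hypoxia-induced gene, by 1.13 log2 (SE 0.0566), while HK2, encoding hexokinase 2, fell from 216 ± 0.831 to 95.0 ± 0.868 CPM (log2 fold change -1.18, SE 0.0435, adjusted p = 1.52e-15). Lipid genes also split, with 14 rises and 18 falls among 40 (33 over the list alone, median -0.09, mean 0.10, set test down, adjusted p = 0.658): CPT1A rose by 2.50 log2, while PLIN2, which coats lipid droplets, fell from 377 ± 11.8 to 161 ± 2.79 CPM and ACSL1, an acyl-CoA synthetase gene, by 1.46. Wnt targets had 5 rises and 12 falls among 19 (17 over the list alone, median -0.24, adjusted p = 0.0730), DKK1, a secreted Wnt inhibitor, at -1.11.

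Stability under actinomycin D in shCtrl was compared with the change at 0 h, on the hypothesis that RNAs with fast loss depend most on either enzyme. In shMETTL14 the change at 0 h rose with the shCtrl slope over 1, 3 and 6 h, at Spearman rho 0.125 across 10042 genes (0.120 with the GC trend removed), which are not independent; this is consistent with short-lived RNAs being lower there. Over 5 groups of genes, from the least to the most stable, the median log2 fold changes were -0.13, -0.11, -0.07, -0.05 and -0.01. In shSETD2 rho was 0.0447 (0.0757 with the GC trend removed), which did not settle the question. The 0 h shCtrl libraries enter the 0 h change but not the slope. METTL14 knockdown might lower such RNAs through synthesis or decay, and 0.125 does not tell these apart. Labelling of new RNA in both lines would separate synthesis from decay. Other differences between the stable lines were not tested and could give the same pattern.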
